A study of Homo sapiens with 16 samples.

How the data were processed

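ATAC-seq libraries came from MDA-MB-231 cells in 4 groups of 4 samples, ancestral and soft-selected cells on soft (1 kPa) and stiff (308 kPa) gel. Per the labels' protocols, gels were polyacrylamide coated with type I collagen, selection ran for 75 days on soft gel with 20000 cells replated about every 7 days, nuclei came from 200000 cells, and libraries were made on 50000 nuclei with a commercial kit.

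The submitters' processing notes name Trimmomatic 0.36, FastQC 0.11.4, MultiQC 1.1, Bowtie2 2.4.5 and MACS2 2.2.7.1 with the GRCh38 assembly. The authors deposited 1 MACS table per group. Per the file headers, each peak has its start, end, width and summit, the pileup signal at the summit, a −log10 p-value, a −log10 q-value, a fold enrichment and a numbered name. In the deposited values the pileup is a whole number that was not scaled to depth. The deposited fold enrichment equals the pileup plus 1 divided by a background plus 1. This background is a single genome-wide value per list with no local term. It was 16.3 for ancestral cells on soft gel and 20.2 on stiff gel, and 13.5 and 12.6 for selected cells. The selected lists thus stood at 82.6% and 62.4% of the ancestral background on the same gel. The lowest deposited −log10 q-value was just over 2 in each list. How the 4 libraries of a group were combined, the filters and the caller's options are not given in the sources used here. Read totals per sample are not among these columns, and the −log10 p-value was not used here.

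The names number the peaks of each list in order of position, and 1107, 1173, 1311 and 1240 numbers are skipped in the lists of ancestral soft, ancestral stiff, selected soft and selected stiff. The widest listed peaks measure 5650, 5946, 8443 and 7950 bp, and the shortest stretches that hold a skipped number measure 6392, 6699, 9099 and 8607 bp. A peak of another list that overlaps such a stretch and no listed peak was called undetermined.

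The comparisons were selected against ancestral cells on soft gel and on stiff gel, and soft against stiff gel in each population. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Counts and shares of unshared peaks carry exact Clopper-Pearson 95% intervals. The log2 ratio of unshared counts compares the first-named group with the second. Fold enrichment, which is the authors' value over a separate background per list, was used to rank and describe peaks and not tested between lists. The 4 lists were merged into regions on overlap. Regions in exactly 2 lists were set against counts given by list-specific odds alone, and the odds ratio multiplies both matching pairs (soft with soft, stiff with stiff) and divides by both mixed pairs. Chromosomes 1 to 22 and X were compared by their log2 ratio relative to the genome, also in windows of 10 Mb.

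Gene positions came from a table of GRCh38.p14 genes without strand. Each peak summit was assigned to the nearest of 19974 protein-coding genes within 100 kb. A gene had an end peak when any part of a peak lay within 1 kb of either annotated end. The gene ends took the place of the transcription start site that had been planned. The 20 gene lists, the comparisons, the naming rule and the alternatives were fixed before the data were examined, and 426 of 427 unique symbols of the lists were found. For each list, the balance was the first-named-only minus the second-named-only peaks, over all its assigned peaks. It was placed among 10000 random lists matched on the number of assigned peaks. The naming rule took, per direction, the 10 unshared peaks with the highest fold enrichment, at most 1 per nearest gene, gene-list members with an end peak in 1 list only, and up to 4 members per list with the most unshared peaks. After the skipped numbers were found, the rule was repeated without undetermined peaks. The other unshared peaks within 5 Mb of the middle of a named gene, genes and windows with the most unshared peaks, and the strongest regions of a pair of lists, were chosen after their values were seen.

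Alternatives were 50% coverage of the shorter peak, a 500 bp gap counted as shared, peaks with −log10 q of at least 10, the top 54789 peaks of each list, regions merged within 500 bp, gene assignment within 10 kb, gene ends within 3 kb and, added after the data were seen, the exclusion of undetermined peaks or regions. Work was done in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: in 109578 peaks of ancestral cells on soft gel, all 5000 planted absent peaks were recovered with 0 false ones, and all 1096 peaks removed by width were located. The odds ratio was 0.996 in 160000 simulated regions without a tie between lists. These regions were drawn with list-specific odds that act alike on all regions, so this checks the computation only. Motif searches had been planned and were not run, because the reference used here holds no genome sequence. No paired analysis was possible because the lists give no values per sample. Results of 1 gene list and of some single genes are not reported here. Names and annotated pseudogenes were taken from the same gene table.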

Results

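Accessible chromatin was mapped by ATAC-seq, in which a transposase cuts open DNA, in MDA-MB-231 cells, an established line from a human breast adenocarcinoma. The 16 samples formed 4 groups of 4: ancestral cells and cells selected on soft gel, each grown on soft gel (1 kPa) and on stiff gel (308 kPa). The deposited data hold 1 peak list per group, with positions on GRCh38. Ancestral cells had 109578 peaks on soft gel and 116043 on stiff gel, and selected cells had 129755 and 122591. The peaks covered 118 Mb, 129 Mb, 154 Mb and 139 Mb in the same order. Read totals per sample are not in the files. The background pileup against which enrichment was computed is the only depth measure, at 16.3, 20.2, 13.5 and 12.6 fragments in that order. Median fold enrichment, which each list gives over its own background, was lower in selected cells, at 3.59 on soft gel and 4.19 on stiff gel, than in ancestral cells, at 6.47 and 6.27. The share of peaks with −log10 q of at least 10 was 78.7% and 81.4% in the ancestral lists and 57.5% and 63.2% in the selected lists. With 1 list per group there is no spread between replicates and no p-value between groups. The 95% intervals given cover counting error only. They are exact Clopper-Pearson intervals, except those of odds ratios, which use a normal approximation for the log odds ratio.

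Each list skips 1.00% of its own peak numbers, and the stretches that hold a skipped number are all longer than the widest listed peak. A peak without a partner at such a stretch of the other list is called undetermined here. The rule for naming peaks picked 10 per direction in each comparison, and all 10 were undetermined in every direction. They included peaks at SRF, JUN, ATF3, MYH9, TLN1 and EEF1A1. The peaks named in the following paragraphs come from the same rule applied to the other peaks, and counts of peaks per gene leave undetermined peaks out.

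Cells selected on soft gel were compared with ancestral cells on soft gel to look for differences in accessibility after selection. The members of the gene lists with the most unshared peaks were named, which gives no result for a list as a whole. VAV2 had 54 selected-only peaks and 0 ancestral-only peaks, and PTK2, which encodes focal adhesion kinase, had 39 and 1. COL5A1, a fibrillar collagen gene, had 40 and 5, and the YAP/TAZ target ASAP1 had 37 and 10. Ancestral-only peaks prevailed at other list members, with 9 against 0 at CRIM1, 9 against 1 at RBMS3 and at ARHGAP42, 6 against 0 at AMOTL2 and DLC1, 7 against 2 at LAMA3 and 6 against 1 at CD44. Several of these counts went with their surroundings and were not particular to the gene: the other peaks within 5 Mb numbered 773 selected-only and 46 ancestral-only around VAV2, 548 and 21 around PTK2, 672 and 38 around COL5A1, 378 and 64 around ASAP1, and 18 and 66 around CRIM1. Around DLC1, with 62 and 44, they did not go the way of the gene.

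As a group, extracellular matrix genes stood at percentile 0.68 of random gene lists with as many peaks. A low percentile means few selected-only relative to ancestral-only peaks. Without undetermined peaks the percentile was 0.09, and 18 of the 29 matrix genes had more ancestral-only than selected-only peaks while 6 had more selected-only ones. YAP/TAZ-TEAD target genes stood at percentile 3.61, at 15.3 with genes assigned within 10 kb and at 0.38 without undetermined peaks. AP-1 family genes stood at 93.1, at 99.7 with genes assigned within 10 kb and at 44.9 without undetermined peaks. Focal adhesion and integrin genes stood at 4.00, and actin cytoskeleton and SRF/MRTF target genes at 33.7. Among mesenchymal and EMT genes, which stayed inside 2.5 to 97.5 as a list, TWIST1, TWIST2, CDH2 and FOXC2 had a peak within 1 kb of a gene end in selected cells and none in ancestral cells. The same held for CDH1, for the actin-binding gene TPM1, the integrin gene ITGA11, the channel genes TRPV2 and TRPV4, MMP10, VAV3, TFF3 and SOX10. GRHL2, MMP7, CCL5 and IL1A had such a peak in ancestral cells only. Among blood cell markers, CD3D, TAL1, LCK and PAX5 had an end peak in selected cells only. Over all protein-coding genes, 1113 had an end peak in selected cells only and 302 in ancestral cells only.

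In total, 46400 selected-cell peaks on soft gel had no ancestral partner, 35.8% of the list (35.5% to 36.0%), against 23724 ancestral peaks without a selected partner, 21.7% (21.4% to 21.9%). The log2 ratio of these counts was 0.97 (0.95 to 0.99), and it was −1.10 among peaks with −log10 q of at least 10. Unshared peaks were weaker than shared ones in both lists: without undetermined peaks, the median fold enrichment was 2.56 for selected-only peaks against 5.66 for shared peaks of that list, and 3.47 for ancestral-only peaks against 9.13. Selected-only peaks lay inside genes in 60.2% of cases, against 36.1% of ancestral-only peaks. The strongest selected-only peak lay 103 kb from SLCO3A1 (chromosome 15, 91749487 to 91751202) with a fold enrichment of 26.9. It was followed by peaks near ANKRD46, in RGPD2 over annotated mitochondrial pseudogenes, and in CDH4. The strongest ancestral-only peak lay in SUN1, which encodes a protein of the nuclear envelope (chromosome 7, 816371 to 816712; fold enrichment 49.6), followed by PNPLA8, a peak near KCNA5, and ELK1.

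**Figure D1:**
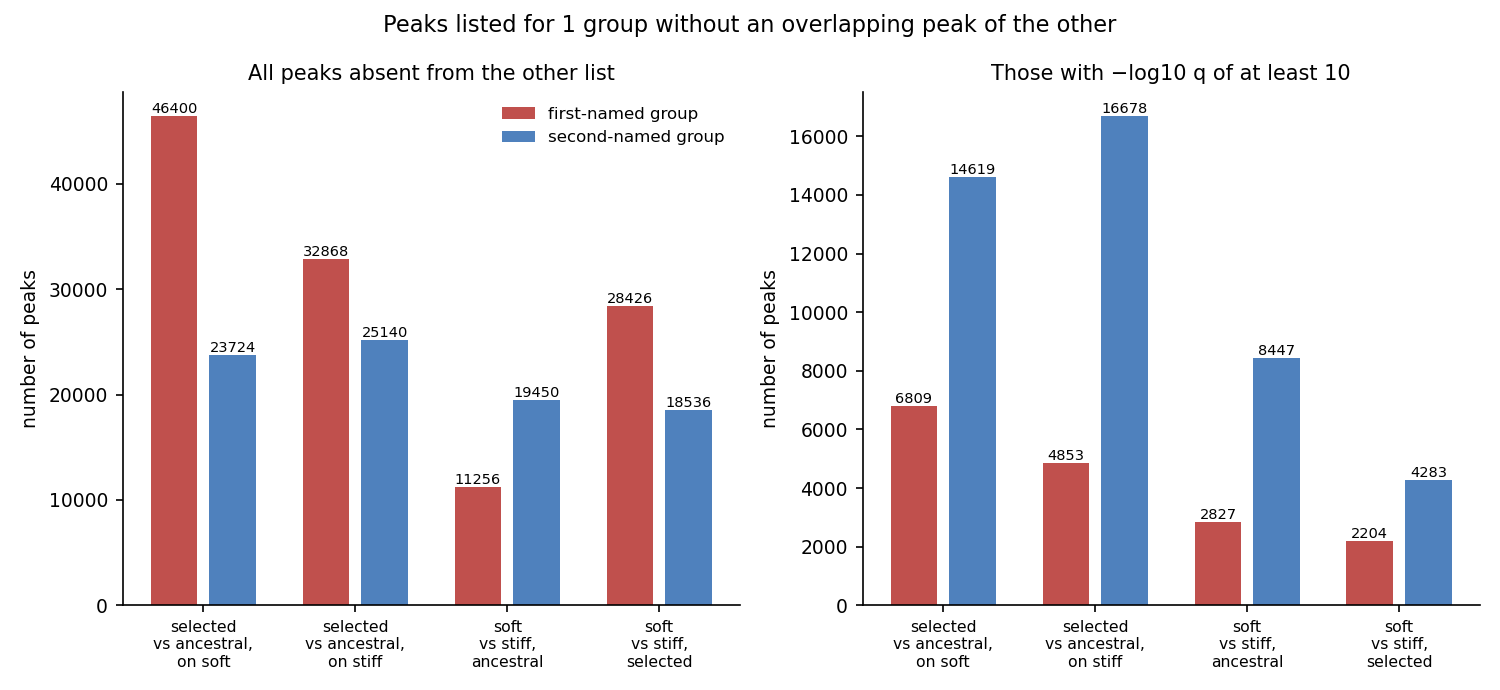
Number of peaks of each group without an overlapping peak of the compared group, for all peaks (left) and for those with −log10 q of at least 10 (right). Selected cells had more unshared peaks than ancestral cells among all peaks (46400 against 23724 on soft gel) and fewer among strong peaks (6809 against 14619).

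The same populations were compared on stiff gel. Gains at VAV2 (49 selected-only peaks and 2 ancestral-only), COL5A1 (32 and 6), ARHGEF17 (14 and 0), PTK2 (16 and 2) and SRC (19 and 0) were also present there. Losses fell on CRIM1, with 0 selected-only and 11 ancestral-only peaks, on TGFB2 with 0 and 9, on MYLK with 0 and 7, and on TPM1 with 1 and 7. The gene of the smooth-muscle myosin kinase (MYLK) and the tropomyosin gene TPM1 belong to the contractile machinery. ACTN1 of the same gene list went the other way, with 14 selected-only and 5 ancestral-only peaks. The surroundings within 5 Mb went the way of the gene around VAV2 (663 selected-only and 63 ancestral-only peaks), SRC (573 and 69) and CRIM1 (12 and 90). They also did so around COL5A1 (582 and 55), ARHGEF17 (532 and 66), PTK2 (517 and 21) and TGFB2 (13 and 73), but not around ACTN1 (72 and 82). Around TPM1 they numbered 39 and 98, and around MYLK they were nearly even, at 73 and 82. ASAP1, with more selected-only peaks on soft gel, was mixed on stiff gel, with 11 selected-only and 14 ancestral-only peaks.

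YAP/TAZ-TEAD target genes stood at percentile 0.97 of random lists in this comparison, and 14 of 22 members had more ancestral-only peaks against 6 with more selected-only ones. Actin cytoskeleton and SRF/MRTF target genes stood at 15.8, and at 1.56 without undetermined peaks, and extracellular matrix genes at 5.43. At gene ends, TWIST1, TWIST2, CDH2, FOXC2, TPM1, ITGA11, SOX10, CD3D and LCK had a peak in selected cells only on stiff gel, as on soft gel. FHL2, PIEZO2, MMP1, ADAMTS5, CCL5, FDFT1, TBX21 and NEUROD6 had one in selected cells only on stiff gel and not on soft gel. FHL1, CDH1, ARHGAP29, BATF, MMP7 and KRT5 had one in ancestral cells only. The end peak of the E-cadherin gene CDH1 was thus listed in selected cells only on soft gel and in ancestral cells only on stiff gel. CCL5 had the reverse pattern. These are calls of presence in single lists, and whether such peaks lie near the calling threshold was not examined. On stiff gel 829 genes had an end peak in selected cells only and 312 in ancestral cells only.

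Of the selected-cell peaks on stiff gel, 32868 had no ancestral partner (26.8%, 26.6% to 27.1%), and 25140 ancestral peaks had no selected partner (21.7%, 21.4% to 21.9%). The log2 ratio was 0.39 (0.36 to 0.41) and, among peaks with −log10 q of at least 10, −1.78. The strongest selected-only peaks lay in PCBD2 (over the mitochondrial pseudogene MTND4P12), near SLCO3A1 and near ANKRD46. The strongest ancestral-only peak lay 338 kb from MKI67 (chromosome 10, 128464363 to 128464634; fold enrichment 49.2) and, at 272 bp, had the smallest width in its list. It was followed by peaks near MBOAT2 and in SHROOM3, an actin-binding gene of epithelial cell shape, whose peak (chromosome 4, 76624205 to 76624753; fold enrichment 22.4) was present in both ancestral lists and in neither selected list.

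Soft and stiff gel were compared within ancestral cells. Stiff-only peaks outnumbered soft-only peaks over the genome. Of single list members, ACTN1 had 11 stiff-only peaks and 1 soft-only peak, MYH9 had 7 and 0, TPM1 had 6 and 0, and COL1A1 had 7 and 0. PIEZO1 and TRPV4, which encode mechanosensitive channels, had 5 and 0 each, and MMP16 had 8 and 0. TGFB2, a YAP/TAZ target gene, had 7 stiff-only peaks and 1 soft-only peak. VAV2 had 22 stiff-only and 6 soft-only peaks. The other peaks within 5 Mb leaned the same way, with 69 stiff-only and 14 soft-only around ACTN1, 112 and 10 around MYH9 and 67 and 1 around TPM1. They numbered 111 and 29 around COL1A1, 141 and 21 around PIEZO1, 88 and 35 around TRPV4 and 39 and 18 around MMP16. Around TGFB2 they numbered 45 and 13, and around VAV2 265 and 119. The counts at these genes were thus not shown to be particular to them.

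Matrix protease genes stood at percentile 2.02 of random lists (low for few soft-only relative to stiff-only peaks). They stood at 2.99 with genes assigned within 10 kb and at 8.26 without undetermined peaks. Mechanosensitive channel genes stood at 19.3, and at 2.24 without undetermined peaks. Actin cytoskeleton and SRF/MRTF target genes stood at 10.8 and extracellular matrix genes at 53.4. Sterol synthesis genes stood at 93.5, and at 99.2 with genes assigned within 10 kb, and interferon response genes at 96.4. YAP/TAZ-TEAD target genes stood at 26.9. FHL1, BGN, CDH1, ARHGAP29, TRPV2, TRPV4, TFF3, KRT5 and PAX5 had an end peak on stiff gel and none on soft gel, while CCL5 and TBX21 had one on soft gel only. In all, 408 genes had an end peak on stiff gel only and 132 on soft gel only. Unshared peaks numbered 11256 for soft gel (10.3%) and 19450 for stiff gel (16.8%), a log2 ratio of −0.79 (−0.82 to −0.76). The strongest soft-only peaks lay in PCBD2 and DPP6, both also present in the 2 selected lists, and the strongest stiff-only peaks lay near MKI67, in SBF2 and near MZF1. FBN1 and EML1 followed, with peaks on stiff gel in both populations and on soft gel in neither.

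Within selected cells, soft gel added peaks at ASAP1 (38 soft-only and 6 stiff-only), PTK2 (30 and 4), TNS3 (26 and 7), NUP153 (13 and 1) and INSIG1 (10 and 0). ASAP1 and PTK2 lie past 130 Mb of chromosome 8, where selected cells had 528 soft-only and 136 stiff-only peaks in all, so their counts were not particular to these genes. Around NUP153, the other peaks within 5 Mb numbered 316 soft-only and 51 stiff-only. Around INSIG1 they numbered 437 and 114, and around TNS3 93 and 61, so these surroundings leaned the same way. TNS3 encodes a tensin of cell adhesions, and INSIG1 a regulator of sterol synthesis. Stiff gel added peaks at MYH9 (2 soft-only and 8 stiff-only), DLC1 (1 and 7), RBMS3 (0 and 7), AMOTL2 (0 and 4), COL8A1 (0 and 4), LSS (0 and 7) and MCM5 (0 and 6). The other peaks within 5 Mb also leaned to stiff gel around LSS (51 soft-only and 215 stiff-only), MYH9 (75 and 121) and MCM5 (83 and 120). Those around COL8A1 (20 and 36) and AMOTL2 (24 and 40) leaned the same way. Around DLC1 (34 and 37) and RBMS3 (33 and 35) they were nearly even. AMOTL2 encodes an angiomotin that is a YAP/TAZ target.

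Hypoxia and glycolysis genes stood at percentile 0.60 in selected cells, luminal breast markers at 0.36 and extracellular matrix genes at 1.23. Each had few soft-only relative to stiff-only peaks. Without undetermined peaks the 3 percentiles were 4.94, 1.84 and 0.38. FHL2, BGN, GRHL2, PIEZO2, MMP1, ADAMTS5, CCL5, IL1A, FDFT1 and NEUROD6 had an end peak on stiff gel only, and CDH1, VAV3, BATF, MMP10 and TAL1 on soft gel only. The counts were 352 genes with an end peak on soft gel only and 333 on stiff gel only. Unshared peaks numbered 28426 for soft gel (21.9%, 21.7% to 22.1%) and 18536 for stiff gel (15.1%, 14.9% to 15.3%), a log2 ratio of 0.62 (0.59 to 0.64); among peaks with −log10 q of at least 10 it was −0.96. The strongest soft-only peaks lay over 100 kb from any protein-coding gene, nearest to LINC02798 and WSB1, and the strongest stiff-only peaks lay at GNG7, in ANKRD28 and at SIK1.

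Across the 4 comparisons, 7 of 80 percentiles fell outside 2.5 to 97.5, and 8 did so without undetermined peaks. Chance would give 4 if random lists were like these in all but the genes, which is only a rough guide. The random lists were matched on the number of peaks and not on position or gene density, and the comparisons share peak lists. Whether a percentile reflects where the genes of a list lie was not tested. Several other gene groups stayed inside these bounds in the main run. Their percentiles ranged from 11.4 to 75.9 for mesenchymal and EMT genes, 44.5 to 71.3 for epithelial genes, 33.2 to 93.4 for nuclear envelope and LINC complex genes, 9.07 to 68.5 for NF-kB and inflammatory cytokine genes, 29.1 to 83.6 for cell cycle genes and 15.4 to 72.9 for basal and myoepithelial markers. With genes assigned within 10 kb, basal and myoepithelial markers fell outside, at 1.31 in soft against stiff gel in selected cells. Blood cell markers ranged from 14.6 to 90.8 and neuron markers from 45.4 to 91.4, both highest in selected against ancestral cells. RBFOX3, a neuronal splicing gene, had 79 selected-only and 3 ancestral-only peaks on soft gel, with 717 and 42 others within 5 Mb.

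**Figure D2:**
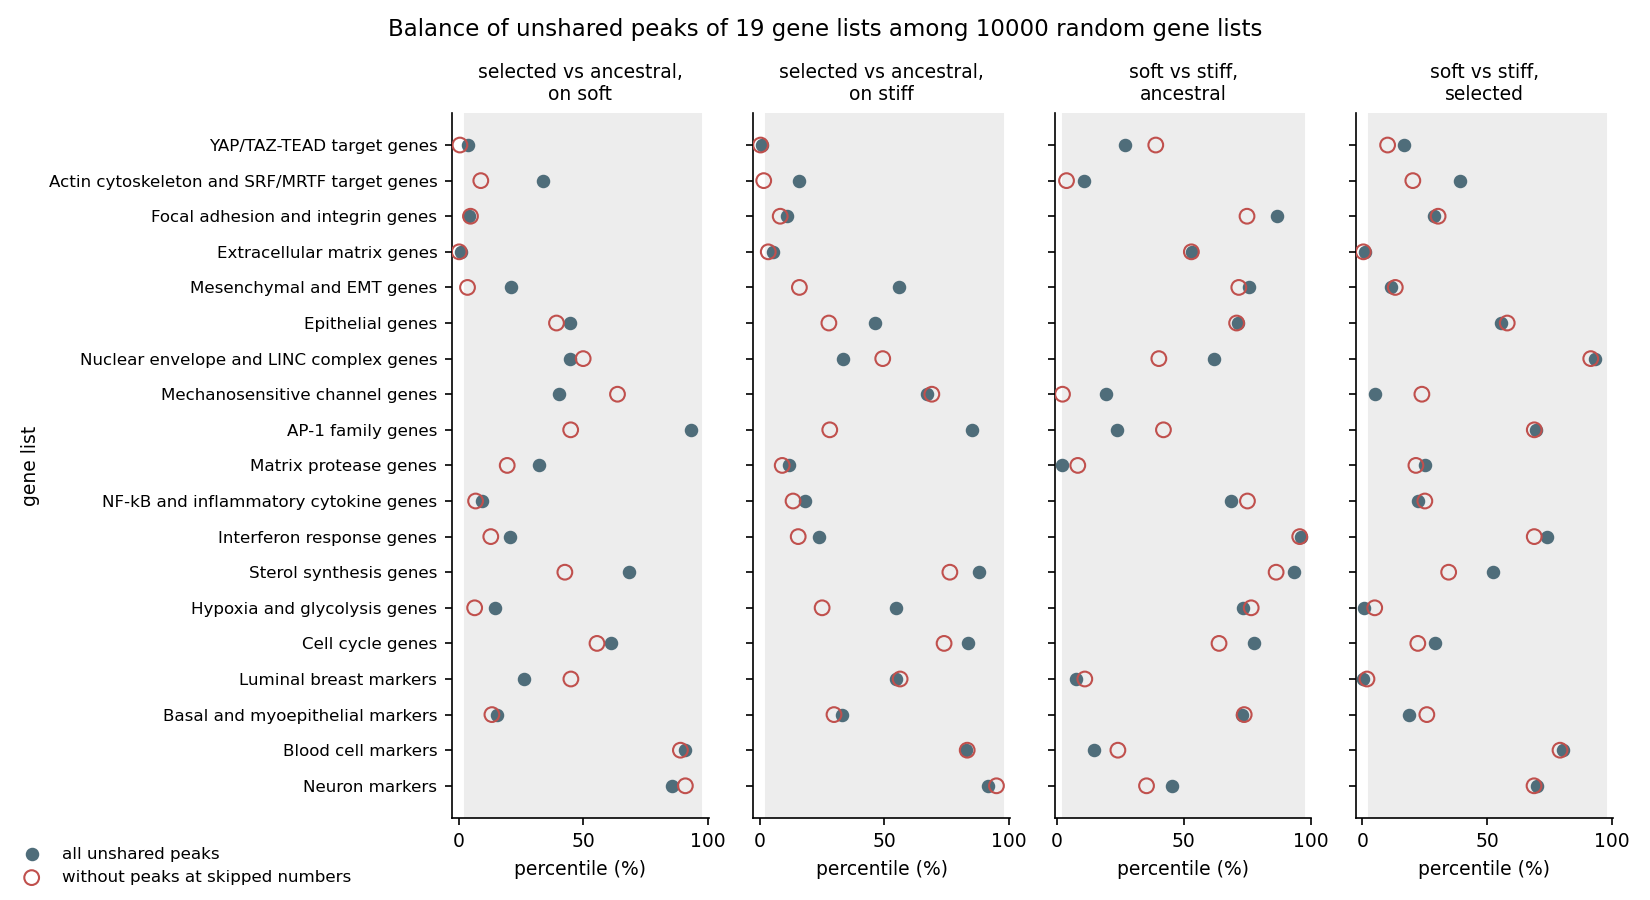
Percentile of the balance of unshared peaks of 19 gene lists among 10000 random gene lists, in each comparison, for all unshared peaks (filled) and without peaks at skipped numbers (open); the grey band spans 2.5 to 97.5. Extracellular matrix genes stood at 0.68 in selected against ancestral cells on soft gel and at 1.23 in soft against stiff gel in selected cells.

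Merging the 4 lists gave 164016 regions, of which 71596 (43.7%) had a peak in all 4. Regions with a peak in both selected lists and neither ancestral list numbered 15936, which was 1.89 times the number given by the odds of each list alone. They were most numerous at TRAPPC9 (70 regions), CDH4 (62), GSE1 (58) and PRDM16 (55), counted without undetermined regions. Regions in both ancestral lists only numbered 10476, or 3.50 times the expected number, with 12 at TENM3, 11 at CDH13 and 10 at INPP4B and KCNIP4. With −log10 q of at least 10 in every list the order turned, at 6.51 times for the selected pair and 1.43 times for the ancestral pair. By construction, both pairs exceed their expected numbers by the same number of regions. In the main run these expected numbers were 8452.7 for the selected pair and 2992.7 for the ancestral pair. The order of the ratios thus shows which pair had the smaller expected number, and not which population's lists were more alike. Both stiff lists alone shared 1913 regions and both soft lists alone 1286, against 639 (ancestral soft with selected stiff) and 1359 (ancestral stiff with selected soft) for the mixed pairs. All 4 lay below the number given by the odds of each list, at 0.357, 0.272, 0.136 and 0.252 times in that order, so the soft pair was close to the larger mixed pair. The odds ratio of matching over mixed stiffness was 2.83 (2.52 to 3.19). Among the strongest regions of both stiff lists were ones in EML1, COL8A1, a collagen gene, and SLC7A11, a cystine transporter gene, and one 43.3 kb from MRTFB, which encodes an SRF cofactor.

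**Figure D3:**
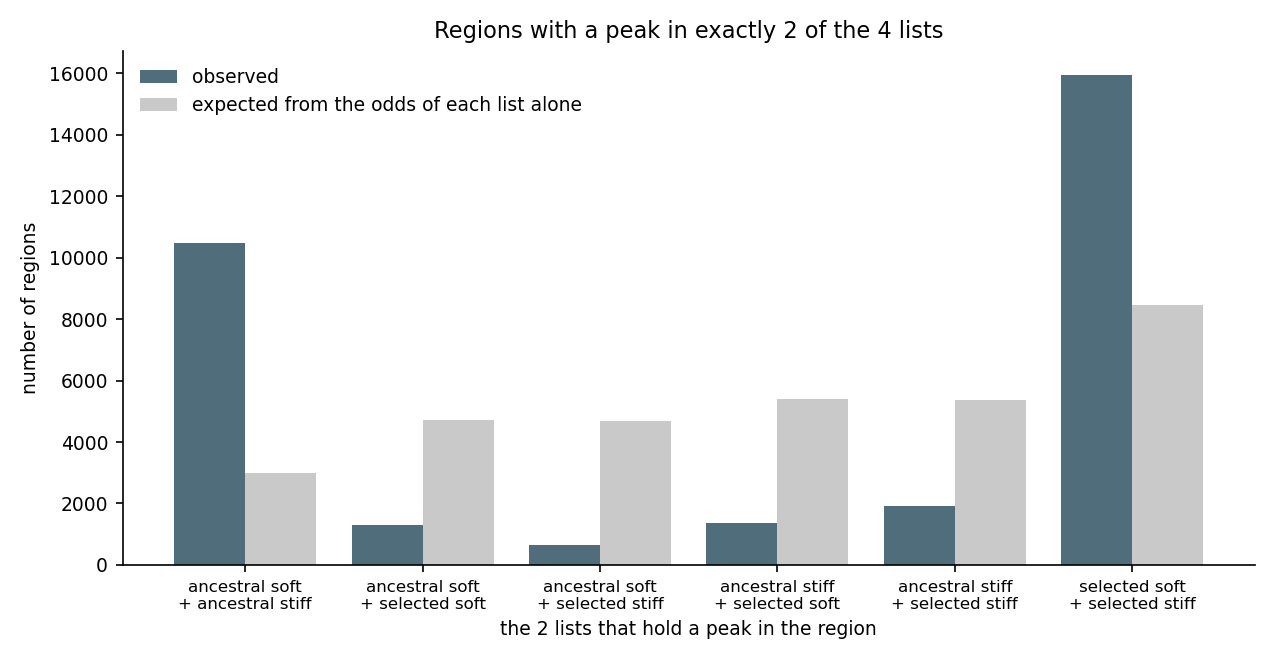
Number of regions with a peak in exactly 2 of the 4 lists, for each pair of lists, as observed and as given by the odds of each list alone. The pairs from 1 population stood above that number (10476 and 15936 regions), and the pair ancestral soft with selected stiff was the smallest, at 639.

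Regions that ancestral cells had on stiff gel and lacked on soft gel numbered 16451. Selected cells on soft gel had a peak in 37.9% of them (37.1% to 38.6%) and selected cells on stiff gel in 41.2% (40.5% to 42.0%). Of the 9498 regions that ancestral cells had on soft gel only, 40.6% (39.7% to 41.6%) had a peak in selected cells on soft gel and 33.8% (32.9% to 34.8%) in selected cells on stiff gel.

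Unshared peaks were uneven over the chromosomes. Chromosome X had 170 selected-only and 898 ancestral-only peaks on soft gel, a log2 ratio of −3.37 (−3.61 to −3.13) relative to the genome, and 136 and 1058 on stiff gel, at −3.35 (−3.61 to −3.09). These ratios cover unshared peaks only. Counting shared peaks too, X held 1571 peaks in selected and 2252 in ancestral cells on soft gel, and 1720 and 2564 on stiff gel. The ratio of unshared peaks on X was also below the genome in soft against stiff gel, at −1.57 in ancestral cells and −1.88 in selected cells. In selected against ancestral cells on soft gel, chromosomes 13, 18 and 4 stood at −1.99, −1.90 and −1.69, and chromosomes 17, 19 and 20 at 0.97, 0.90 and 0.77; on stiff gel these were −1.52, −1.08, −1.35, 0.87, 1.18 and 1.15. Chromosome 21 stood at −1.16 on soft gel and at 0.05 on stiff gel. Within selected cells it was lower on soft gel, at −1.91 (−2.17 to −1.66).

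**Figure D4:**
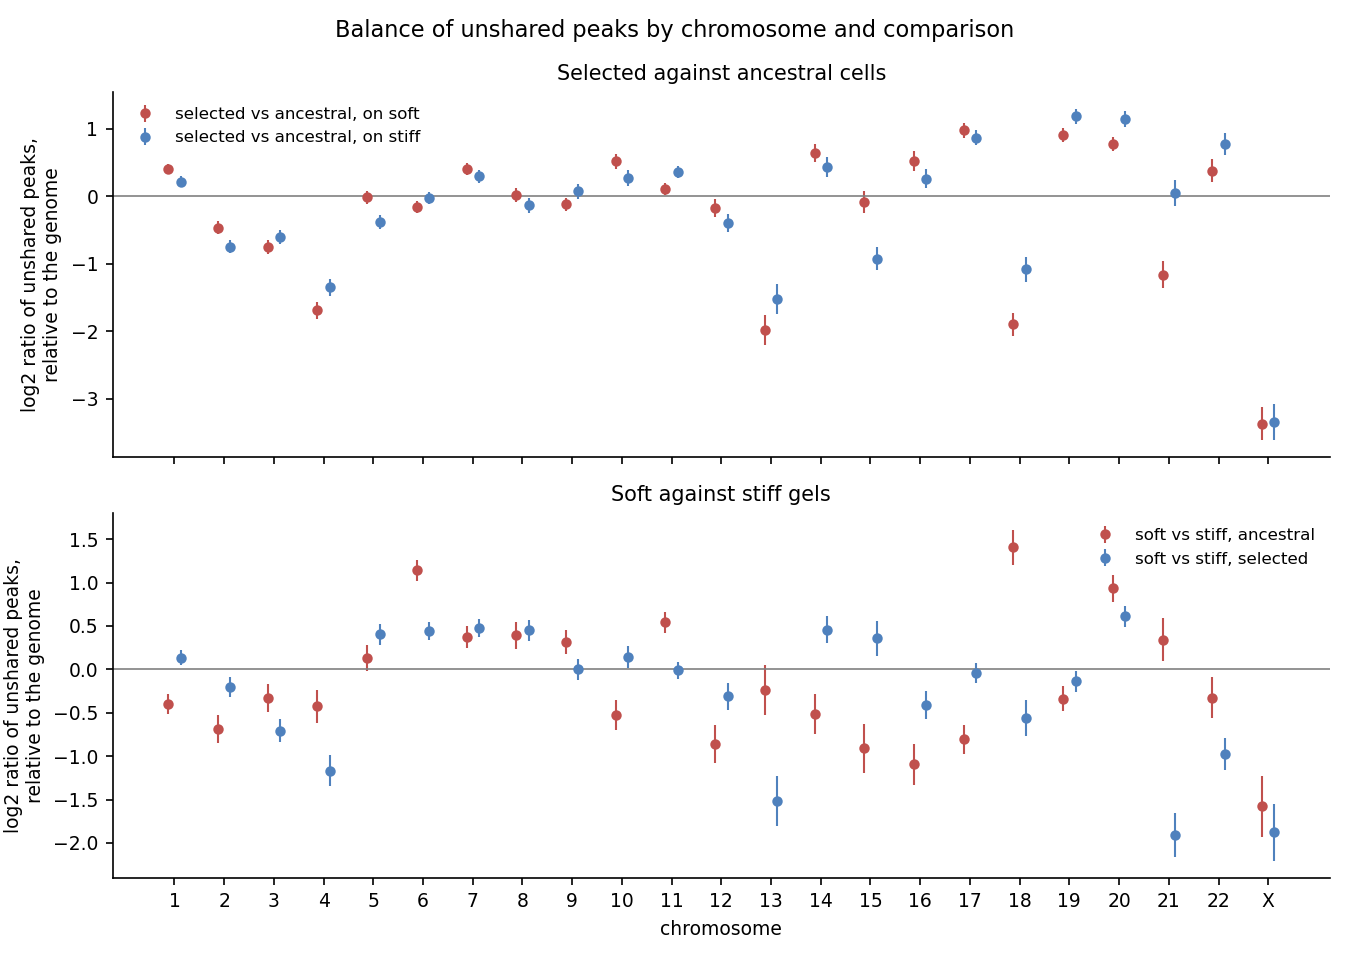
Log2 ratio of unshared peaks per chromosome, relative to the whole genome, in selected against ancestral cells (top) and in soft against stiff gel (bottom); bars are 95% exact intervals. Chromosome X was below 0 in all 4 comparisons, at −3.37, −3.35, −1.57 and −1.88.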

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

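All tests of explanations in this part were chosen after the results were seen.

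Soft gel had fewer unshared peaks than stiff gel in ancestral cells (log2 ratio −0.79) and more in selected cells (0.62), a difference between populations that was not tested. Among peaks with −log10 q of at least 10 the ratios were −1.58 and −0.96, so the directions did not differ there. Chromosome 18 stood at 1.40 in soft against stiff gel in ancestral cells and at −0.56 in selected cells, relative to the genome, and this difference was not tested either. Without undetermined peaks, its part from 16 to 20 Mb stood at 4.57 in ancestral and 1.25 in selected cells, and the rest at −0.19 (−0.49 to 0.11) and −1.19, so the 1.40 came from that part. The numbering in the peak names, which no comparison was planned to use, skips 1107, 1173, 1311 and 1240 numbers in the lists of ancestral soft, ancestral stiff, selected soft and selected stiff.

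The strongest unshared peaks, among them those at SRF, JUN, ATF3 and MYH9, lay where the other list skips numbers. Of the stretches that hold a skipped number, 100% were longer than the widest listed peak, against 71.8% after random removal of as many peaks, which is in line with a removal of the widest peaks from each list. Of the 800 strongest unshared peaks, 799 lay at skipped numbers. Of all peaks, shared or not, 1.41% to 4.33% did so, depending on the list and the comparison. For these peaks as a set, this argues against absence of the peak in the other cells as the main cause. In 37.8% (34.4% to 41.3%) of the 799, the stretch left no room beside the peak for another as wide as the widest listed. A removed peak of that width would overlap such a peak. Single peaks, such as those at SRF or JUN, stay open because the widths and positions of the missing peaks are not listed.

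Regions of both stiff lists (1913), such as those in COL8A1 and EML1 and near MRTFB, and of both soft lists (1286) together outnumbered the mixed pairs (639 and 1359), though the soft pair alone did not exceed the larger of them. List sensitivity alone gives an odds ratio of 1, and the observed 2.83 (2.52 to 3.19) argues against it. Blocks of the genome that differ between lists and fill whole 10 Mb windows would bring the ratio to 1 within these windows, where it was 2.38 (2.08 to 2.73). Smaller blocks stay open, because they can differ from the rest of their window. Repeats next to centromeres were examined by the ratio within 100 kb of protein-coding genes, which was 2.72 (2.37 to 3.13). This argues against repeats far from genes as the whole cause. Repeats close to genes stay open, because such regions were kept. A response to stiffness common to both populations may remain as a hypothesis, and handling shared by samples on the same gel stays open because the labels give no batch.

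Chromosome X held fewer peaks in both selected lists. After a line in gene density over the autosomes, X was left at −3.02 on soft gel and −3.09 on stiff gel, below the lowest autosome at −0.93 and −0.75, so a trend with gene density is argued against as the whole cause. Weak peaks near the threshold are argued against as well: among the same number of top peaks, the log2 ratio for X was −0.38 and −0.35, below the lowest autosome at −0.22 and −0.18. In soft against stiff gel that ratio for X was −0.02 in ancestral cells and −0.05 in selected cells. Fewer copies of X in the selected cells cannot be told apart from other causes: all 14 windows of 10 Mb with at least 20 unshared peaks lay below the genome on both gels, but so did all 11 and all 6 in soft against stiff gel within ancestral and selected cells.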

How the results depend on the processing

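Exclusion of undetermined peaks or regions was chosen after the data were seen; the other alternatives were planned. Of 125 recomputed values for 45 results, 65 kept to the main value (within its interval; for counts and excesses, within 1.5 times; for percentiles, on the same side of 2.5 and 97.5), 54 moved and 6 changed sign; for those below, the cause was not tested unless stated. No paired analysis was possible because the lists give no values per sample; for the same reason leaving out replicates and a replicate block were not run, and motif windows were not run for want of a genome sequence.

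The direction of the log2 ratio of unshared peaks depended on weak peaks. In the order selected against ancestral on soft, on stiff, soft against stiff in ancestral and in selected cells, the main ratios were 0.97, 0.39, −0.79 and 0.62. With −log10 q of at least 10 they were −1.10, −1.78, −1.58 and −0.96, so 3 changed sign. With the same number of top peaks they were −0.056, −0.13, −0.21 and −0.042; equal list lengths bring this ratio near 0 by construction, so these 3 changes of sign say nothing about weak peaks. In each comparison the longer list had more unshared peaks. The ratio for ancestral cells stayed negative throughout. Unshared counts fell under both by construction, as fewer peaks were counted: with −log10 q of at least 10 to 6809 and 14619, 4853 and 16678, 2827 and 8447, and 2204 and 4283, and with top peaks to 8019 and 8336, 6596 and 7211, 3153 and 3651, and 4779 and 4920. Coverage of 50% gave ratios of 0.95, −0.74 and 0.54 where they moved (soft, ancestral, selected), a 500 bp gap gave 0.34, −0.84 and 0.69 (stiff, ancestral, selected), and exclusion of undetermined peaks gave 1.22, 0.51, −0.91 and 0.69.

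The odds ratio of matching over mixed stiffness was 2.83, and 4.83 with −log10 q of at least 10 in every list; merging within 500 bp gave 3.01 and exclusion of undetermined regions 3.08. With the stricter q the ratio of observed to expected regions fell from 3.50 to 1.43 for the ancestral pair and rose from 1.89 to 6.51 for the selected pair. Both pairs exceed expectation by the same number of regions by construction, so this reversal reflects their expected numbers only. Of stiff-only regions of ancestral cells, the share found in selected cells went from 37.9% to 28.7% on soft gel and from 41.2% to 35.7% on stiff gel with −log10 q of at least 10, and to 36.5% and 39.6% with merging. For soft-only regions it went from 40.6% to 32.6%, 42.5% with merging and 42.7% without undetermined regions on soft gel, and from 33.8% to 27.2% and 34.9% on stiff gel. Chromosome X kept its direction in all runs, at −2.90, −2.84 and −1.21 with the stricter q (soft, stiff, ancestral) and −3.89 and −3.80 without undetermined peaks (soft, stiff). Percentiles outside 2.5 to 97.5 numbered 7, 9 with genes within 10 kb and 8 without undetermined peaks. The selected lists have a lower background pileup and a lower share of strong peaks; an effect of depth was not tested.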

Other observations

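The genes, windows and blocks in this part, and the test of the YAP/TAZ target genes, were chosen after the values were seen. Counts of peaks and regions in this part leave undetermined ones out.

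The genes with the most unshared peaks were not tested for an excess over their length. On soft gel TRAPPC9 had 158 selected-only and 0 ancestral-only peaks, PTPRN2 had 133 and 10, SHANK2 had 118 and 8, CDH4 had 107 and 3, and GSE1 had 89 and 3. On stiff gel CDH4 had 136 and 4, PTPRN2 had 136 and 5 and TRAPPC9 had 127 and 2. Ancestral-only peaks were highest in number on soft gel at TENM3 (19 against 1), KCNIP4 (16 against 0) and HDAC9, INPP4B, LIMCH1, NHS and PALLD (14 against 0 each). NEDD4L had 16 stiff-only and 0 soft-only peaks in selected cells.

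The regions of both selected lists and neither ancestral list lay inside genes in 62.8% of cases, against 38.4% for regions of both ancestral lists only. Near blood cell markers, 19 regions were of the selected pair and 0 of the ancestral pair, and near neuron markers 46 and 11. Near extracellular matrix genes the counts were 19 and 29, and near YAP/TAZ-TEAD target genes 22 and 31. The selected pair made up 69.7% of such regions within 100 kb of all genes. The strongest regions of the ancestral pair lay in SHROOM3 and SYN3 and near ACKR3 and PRDM1.

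On chromosome 6 from 34 to 44 Mb, which holds LRFN2, DAAM2 and ZFAND3, peaks were more frequent on soft gel in both populations, with 516 soft-only and 147 stiff-only peaks in ancestral cells and 583 and 170 in selected cells. Selected cells also exceeded ancestral cells there, with 970 peaks against 91 on soft gel and 977 against 65 on stiff gel. At the end of chromosome 8, past 130 Mb, selected cells had 894 peaks against 62 on soft gel and 688 against 84 on stiff gel. On chromosome 21 from 40 to 48 Mb, near PCBP3, ABCG1 and PCNT, selected cells had 51 soft-only and 222 stiff-only peaks, and ancestral cells 35 and 144. From 14 to 40 Mb the counts were 30 and 108 in selected cells and 13 and 96 in ancestral cells.

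Soft-only peaks of ancestral cells were frequent in some windows. The window from 16 to 18 Mb of chromosome 18 had 209 soft-only and 21 stiff-only peaks, that from 52 to 54 Mb of chromosome 11 had 173 and 20, and that from 58 to 60 Mb of chromosome 6 had 126 and 9. In selected against ancestral cells on soft gel the same windows had 13 and 183, 17 and 222, and 12 and 224. Whether the signal in these windows comes from repeats next to centromeres was not tested, because the reference used here holds no genome sequence. Of the 1163 regions in both soft lists only, 291 lay over 1 Mb from any protein-coding gene, against 16 of 1763 in both stiff lists only.

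Balance in 10 Mb windows followed gene number: across windows, which are not independent replicates, Spearman's rho between protein-coding genes and the log2 ratio was 0.56 on soft gel and 0.54 on stiff gel for selected against ancestral cells. In soft against stiff gel it was −0.24 in ancestral cells and 0.18 in selected cells.

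Opening on stiff gel common to both populations near YAP/TAZ-TEAD target genes was tested as a hypothesis. Of 12 regions near these genes that were in both stiff or both soft lists only, 83.3% (51.6% to 97.9%) were in the stiff lists, against 70.2% for all genes. With 12 regions, this cannot be told apart from the share of all genes.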
